A study of Mus musculus with 5 samples.

How the data were processed

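The libraries are nuclear RNA-seq of mouse retina from animals with a tamoxifen-inducible Cre recombinase under the Aldh1l1 promoter and the NuTRAP reporter. Per the labels' protocols, retinae were homogenised into nuclei, undissociated tissue was spun out, a part of the nuclei was set aside as Input and the remainder went through streptavidin bead capture (INTACT) to give the Positive fraction. The same protocol text opens by naming brain tissue, while the sample source and the homogenised tissue are given as retina. Samples were grouped by the fraction in their titles, which also give the animal number. The replicates are separate animals.

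The authors deposited 1 table of log2 values for the 5 libraries, with 16423 rows and no column of other samples. Per the file headers, gene models are RefSeq and rows were kept where every library of at least 1 of the 2 conditions had a raw value of 5 or more. Per the submitters' processing notes, the genome build was mm10 and DESeq was used, and its version, the aligner and the counting tool are not given in the sources used here. In 8851 genes Input 40 was exactly 0 and in 7182 genes Input 55 was, in 4 both were, and in the other 393 the 2 Input values lay on opposite sides of 0. The deposited log2 values are therefore ratios to an Input level of each gene, which cancels in differences between libraries and in SDs. They hold no expression level, no count and no depth, so no interval for counting error could be given and no count model was used. Of the genes tested, 15671 had passed the filter in both conditions and 751 in 1 of them. Where a gene passed in 1 condition only, the lowest value could be shared by several libraries, as it was (to within 1e-06) in 22 genes, and fold changes of those genes depend on that floor. Whether the counting used strand is not given, so overlapping genes and genes hosted in others, such as microRNA and snoRNA genes, cannot be told from their hosts. Coordinates are those of the deposited table. Of 16373 genes matched by Entrez gene number to RefSeq genes of GRCm38, 16372 overlapped them on the same chromosome.

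Positive was compared with Input by limma 3.58.1 in R 4.3.3 on the deposited log2 values without further normalization or filter, with 3 residual degrees of freedom, empirical Bayes moderation and Benjamini-Hochberg adjustment over 16422 genes, 1 row per symbol (the row with the highest mean). Tests were two-sided, with a threshold of 0.05 on the adjusted p. An exact permutation of 3 against 2 libraries has 10 arrangements and cannot give a p under 0.1, so none was used. The fit was planned with a trend of the variance on the mean level. It was run without the trend, because the means of these values are not expression levels, a change made after the columns were seen and before any test; the fit with the trend is among the alternatives. For each gene the log2 fold change is the Positive mean minus the Input mean, and the SE is limma's moderated one.

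Before the data were examined, 33 gene lists of cell types, pathways and functions were fixed, each needing at least 5 measured members, and 32 were tested. Lists were tested with limma's camera with a preset correlation between genes of 0.01, Benjamini-Hochberg over the lists, and again with the correlation estimated per list and with fry. Also fixed before was which genes to name: Aldh1l1, 16 fixed genes, mostly markers of retinal cell types, the 10 genes up and 10 down with the largest changes past the threshold (0 here), and from each list the 2 members with the highest and the 2 with the lowest log2 fold change. A condition on the mean level in this rule was replaced by having passed the authors' filter in both conditions. Genes with an adjusted p under 0.1, genes called with the random block, sex-linked genes, the genes of the region from Meg3 to Mirg and other members of lists or of Gene Ontology terms named for their size were chosen after their values were seen. Some genes the rule names are not reported here. For 1419 Gene Ontology terms of 15 to 500 genes, taken from the deposited annotation column, camera was run in the same way, and the terms named were picked after the ranking was seen.

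Positive and Input libraries with the same number come from the same animal, per the labels, so they are paired for animals 40 and 55, while Positive 12 has no partner here. Across genes, which are not independent replicates, the deviations from the group means of the paired libraries correlated at r = 0.174 for animal 40 and r = 0.195 for animal 55. The animal was fitted as a fixed block and, with a consensus correlation of 0.514 from limma's duplicateCorrelation, as a random block, both as alternatives. The fixed block takes Positive 12 out of the contrast, since that animal has 1 library, so it changes the libraries compared as well as the block. For fits that camera cannot take, the random block and the robust prior, it was applied to the z-scores of the moderated statistics (limma's cameraPR).

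Other alternatives were median centring, quantile normalization, a mean-variance trend with a robust prior, leaving out each library, other thresholds, and, chosen after seeing the data, the trend alone, the robust prior alone, only genes that passed in both conditions, and leaving out X- and Y-linked genes or genes at a shared floor. Random lists of the same size, 10000 per list, were matched on gene length (end minus start of the gene) or on residual spread. The gene test was checked on simulated noise with the residual spread of each of the 16422 genes, in which 68 genes were changed by a log2 fold change of 0.5, 66 by 1 and 66 by 2. It called 0% of these genes at 0.5, 53.0% at 1 and 69.7% at 2, with 2 false calls. A Müller list shifted by 0.4 in independent noise was called by camera, also with an estimated correlation (adjusted p = 0.0248). The simulated genes were independent, so this does not check the list test on genes that move together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.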

Results

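Nuclear RNA was sequenced from the retinae of mice that carried a tamoxifen-inducible Cre recombinase under the Aldh1l1 promoter together with NuTRAP, a Cre-dependent reporter that puts a biotin tag on the nuclear envelope. Each sample was a pair of retinae from 1 animal. Part of each nuclear suspension was kept as whole-retina nuclei (Input), and tagged nuclei were captured from the remainder with streptavidin beads by the INTACT method (Positive, named as Müller glia in the series' design text). The 5 libraries analysed were Positive from animals 12, 40 and 55 (n = 3) and Input from animals 40 and 55 (n = 2), and Input nuclei of animal 12 were not analysed here. The values, for 16422 genes, are on a log2 scale relative to a per-gene Input baseline. They hold no expression level, and the depth behind each value is unknown.

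The comparison of Positive with Input nuclei asks which transcripts are more abundant in captured nuclei than in nuclei of the whole retina. Markers of Müller glia, the radial glia that span the retina, were higher in Positive nuclei: 30 of 33 measured markers had a positive log2 fold change, with a median of 0.43 (1.35-fold). In 27 of the 33, against 16.7% of all genes tested and 10% by chance, all 3 Positive libraries lay above both Input libraries. The median was 0.37 in Positive 12 set against the mean of the Input libraries, 0.55 within animal 40 and 0.34 within animal 55. Aldh1l1, whose promoter drove the recombinase (Entrez gene 107747, mm10 chromosome 6, 90550848 to 90599171), had a mean log2 value of 0.35 ± 0.20 (SD, n = 3) in Positive and 0.04 ± 0.06 (SD, n = 2) in Input. Its log2 fold change was 0.30 with an SE of 0.14, and it did not pass limma's test over all genes (adjusted p = 0.382). Rlbp1, the retinaldehyde-binding protein of the visual cycle (Entrez gene 19771, chromosome 7, 79374870 to 79387027), had a log2 fold change of 0.44 (SE 0.12; adjusted p = 0.331 in limma). Glul, which encodes glutamine synthetase, had 0.43 (SE 0.14), the glutamate transporter gene Slc1a3 had 0.53 (SE 0.15) and the transcription factor gene Sox9 had 0.44 (SE 0.14). The water channel gene Aqp4 had 0.40 (SE 0.16) and the potassium channel gene Kcnj10 had 0.44 (SE 0.15), and in each of these 7 genes every Positive library lay above both Input libraries. Timp3, a metalloproteinase inhibitor, had the largest log2 fold change of the list at 0.67 (SE 0.10), followed by the Notch target Hes1 at 0.66 (SE 0.17). Slc38a3, a glutamine transporter gene, went the other way, with a log2 fold change of -0.29 (SE 0.09) and all 3 Positive libraries below both Input libraries.

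**Figure D1:**
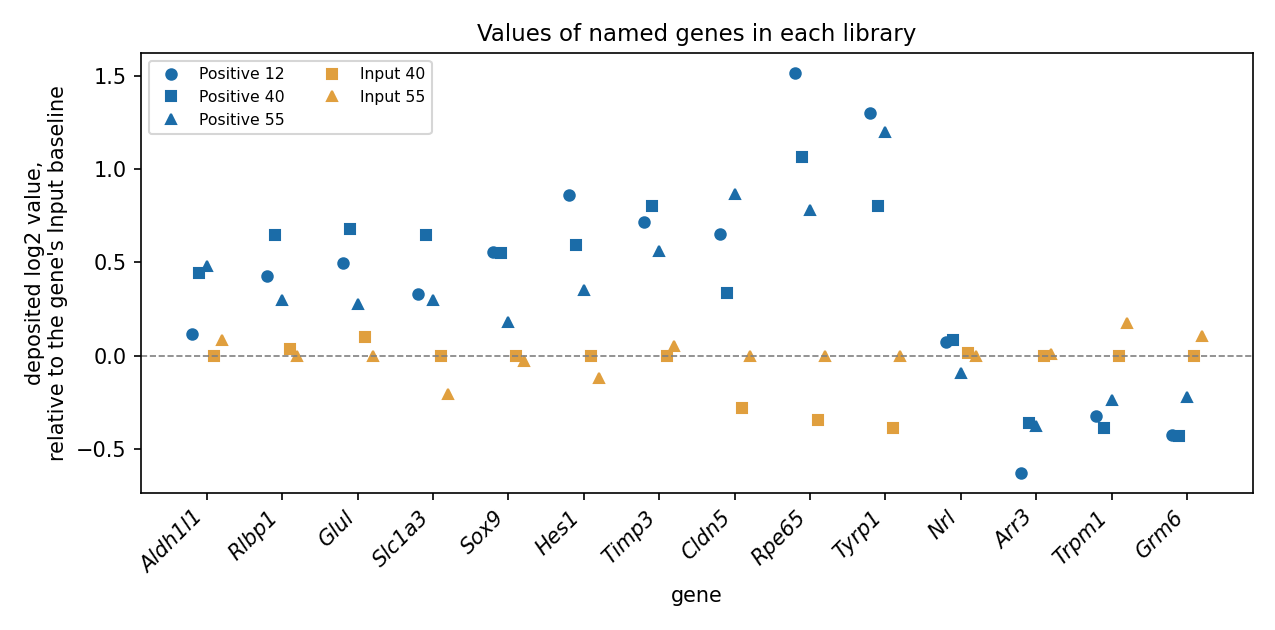
Deposited log2 values, relative to the Input baseline of each gene, of 14 named genes (x axis) in the 3 Positive (blue) and 2 Input (orange) libraries, where each point is 1 library and the symbol gives the animal. The Positive points of Rlbp1, Glul and Slc1a3 lie between 0.28 and 0.68, above both Input points, while those of Nrl lie on either side of the Input points.

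Adjusted over the list alone, 19 Müller markers were higher and 1 lower in limma's test, while over all genes tested 0 of the 33 were called. Limma's camera, which sets a list against all other genes, put the Müller list higher at an adjusted p of 3.00e-12 with a preset correlation between genes of 0.01. The call was lost with the correlation estimated from the data (adjusted p = 0.311 with an estimated correlation). Limma's rotation test fry, which asks whether a list's genes move on balance one way and sets them against no other genes, gave the list an adjusted p of 0.103. With the preset correlation, 20 of the 32 lists tested were higher in Positive and 3 lower, and with an estimated correlation 0 passed, the lowest adjusted p being 0.291. Other splits of the same 5 libraries into 3 and 2 gave up to 17 lists with the preset correlation where both Input libraries stayed together, and 0 to 8 lists where they were parted.

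Over all 16422 genes, limma called 0 genes higher and 0 lower at an adjusted p under 0.05, with a lowest adjusted p of 0.0542. At an unadjusted p under 0.05 there were 2334 genes, 1060 higher and 1274 lower, where chance would give 821. After quantile normalization the split at that threshold was 709 higher and 555 lower. The unadjusted count was 1446 without Positive 40, 1319 without Input 40 and 930 without Input 55. All 3 Positive libraries lay above both Input libraries in 16.7% of genes and below both in 21.8%, where chance gives 10% each. With the animal as a random replicate block, limma called 11 genes, 4 higher and 7 lower, whereas with the animal as a fixed block, which leaves Positive 12 out of the contrast, it called 0.

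The 4 genes higher with the random block were Oca2, Bcas1, Slc25a21 and Gm4922, which were named after their values were seen. Oca2, a melanosome transporter gene needed for pigmentation (Entrez gene 18431, chromosome 7, 56239771 to 56536517), had a log2 fold change of 2.37 (SE 0.13) and Slc25a21, a mitochondrial carrier gene (Entrez gene 217593, chromosome 12, 56712634 to 57197472), had 1.72 (SE 0.08). Without a block their adjusted p in limma was 0.0682 and 0.0542, and with the random block it was 0.0140 for both. Oca2 and Bcas1 had passed the authors' filter in 1 condition only. Bcas1 had a log2 fold change of 2.22 with the random block (SE 0.11; adjusted p = 0.0241 in limma) and Gm4922 had 0.93 (SE 0.06; adjusted p = 0.0498). The 7 lower genes were Ccdc154, Ssxb2, Mir453, AF357355, 1700109G14Rik, Zp1 and A630077J23Rik, with log2 fold changes between -0.85 and -2.07. Of these 7, all but Ccdc154 had passed the authors' filter in 1 condition only. In 5 of them, Ssxb2, Mir453, AF357355, 1700109G14Rik and Zp1, 2 or 3 Positive libraries shared the lowest value of the row, so their fold changes depend on that floor and their SE is not a measure of the spread. Without a block, Oca2, Slc25a21, AF357355, 1700109G14Rik and Ssxb2 were the 5 genes with an adjusted p under 0.1 in limma.

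Markers of retinal neurons stayed near or below the Input level, with the exception of ganglion cells. Rod markers had a median log2 fold change of 0.02 over 20 genes (adjusted p = 0.859 in limma's camera). The rod transcription factor gene Nrl had 0.01 (SE 0.09). The sign of the rod median was not stable, since it was -0.05 after quantile normalization, -0.04 without Positive 12 and with the animal as a fixed replicate block, -0.01 without Positive 40 and 0.09 without Positive 55. Bipolar cell markers had a median of -0.11, with 14 of 17 lower. Adjusted over the list alone 4 were lower, and over all genes 0: Gpr179 (-0.45), Grm6 (-0.41), Trpm1 (-0.41) and Pcp2 (-0.32). The first 3 belong to the light-response pathway of ON bipolar cells. Trpm1 (Entrez gene 17364, chromosome 7, 64153835 to 64269759) had a mean log2 value of -0.32 ± 0.07 (SD, n = 3) in Positive and 0.09 ± 0.13 (SD, n = 2) in Input. The bipolar list passed limma's camera as lower with an adjusted p of 0.0169, and the call was lost with an estimated correlation (adjusted p = 0.394 with an estimated correlation). It was also lost with the fixed replicate block (adjusted p = 0.0889), without Positive 12 (0.0657), without Positive 55 (0.0790), without Input 40 (0.144) and after quantile normalization (0.0909), over a range of 0.00349 to 0.144 in 15 settings. Its median was -0.19 without Positive 40.

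Cone markers had a median log2 fold change of -0.11, with 11 of 15 lower, led by the cone arrestin gene Arr3 at -0.46 (SE 0.11). Adjusted over the list alone and over all genes, 0 cone markers were called. The list's adjusted p in limma's camera was 0.0492 (adjusted p = 0.620 with an estimated correlation). It rose above the threshold with the animal as a fixed (0.345) or random (0.123) replicate block, without Positive 12 (0.177), without Positive 55 (0.219), without Input 40 (0.481), after quantile normalization (0.175), with a mean-variance trend (0.0507, or 0.0615 with a robust prior) and without X- and Y-linked genes (0.0885), over a range of 0.00136 to 0.481 in 15 settings. The median was -0.02 without Positive 12, -0.16 without Positive 40, -0.07 without Positive 55, -0.05 without Input 40 and -0.18 without Input 55. Amacrine markers had a median of 0.01 (adjusted p = 0.757 in limma's camera), which was -0.05 without Positive 40, -0.02 without Input 55, 0.02 without Positive 55 and 0.10 without Input 40. Horizontal cell markers had a median of -0.13 and a mean of -0.01 over 9 genes (adjusted p = 0.654), and the median was 0.07 without Positive 12 and with the fixed replicate block. Shared phototransduction genes had a median of -0.01, or 0.01 after median centring and without Positive 55, and -0.05 without Positive 12 or Positive 40, -0.04 without Input 40, -0.02 without Input 55 and -0.07 after quantile normalization (adjusted p = 0.654). Synaptic vesicle genes had a median of -0.04 (adjusted p = 0.159 in limma's camera, and adjusted p = 0.444 with an estimated correlation), with the presynaptic scaffold genes Bsn and Pclo each at -0.39 (SE 0.10 and 0.11). Without Positive 40 the synaptic list passed as lower (adjusted p = 0.0289, over a range of 0.0289 to 0.556 in 15 settings) with a median of -0.10, and its median was -0.01 without Input 40 and -0.08 after quantile normalization. In the rod, amacrine, horizontal, phototransduction and synaptic lists 0 members were called over the list alone or over all genes. Ganglion cell markers had a median of 0.23, with 12 of 15 higher and 0 called over the list alone or over all genes. Tubb3, a neuronal tubulin gene, had 0.47 (SE 0.10) and Pou4f2, a ganglion cell transcription factor gene, had -0.11 (SE 0.19). The ganglion list's adjusted p in limma's camera was 0.0169 (adjusted p = 0.444 with an estimated correlation), and it was 0.0555 without Positive 40, 0.0586 without Positive 55 and 0.0909 after quantile normalization, over a range of 0.00125 to 0.0909 in 15 settings. These 3 settings gave medians of 0.09, 0.15 and 0.08.

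**Figure D2:**
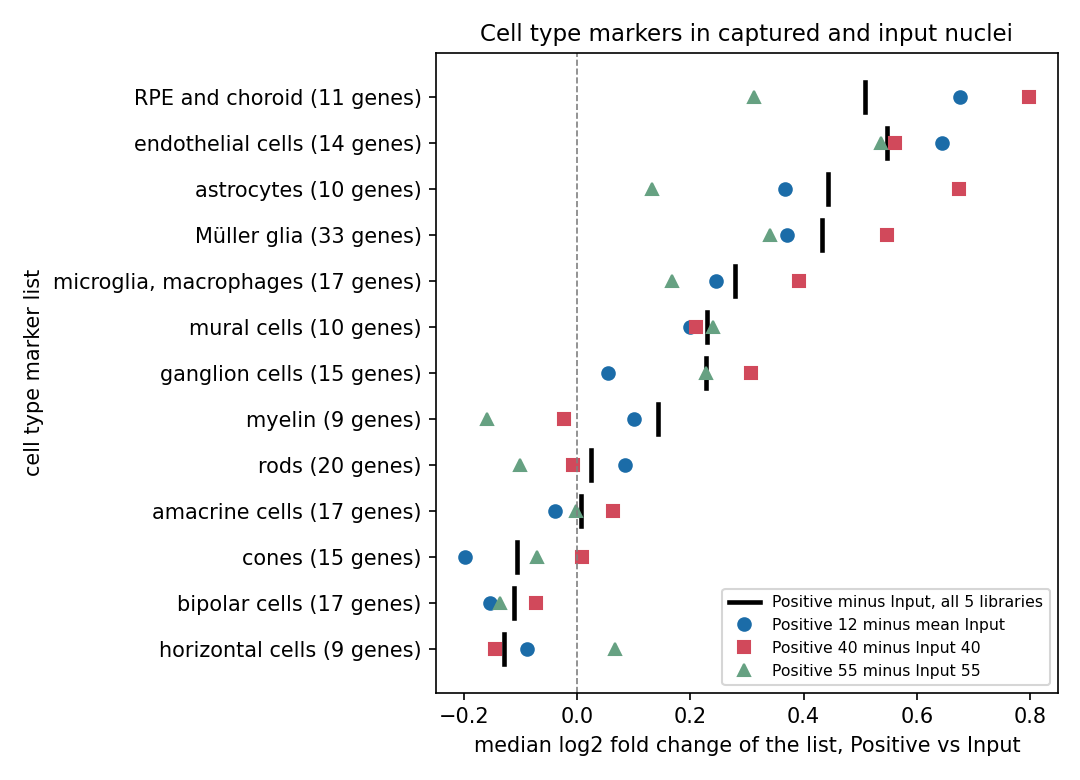
Median log2 fold change of Positive against Input nuclei (x axis) for 13 cell type marker lists (y axis, with the number of genes measured), where the black bar is the median over all 5 libraries and the points give Positive 12 against the mean Input and the within-animal differences of animals 40 and 55. For the Müller list the 3 points lie between 0.34 and 0.55, and for rods between -0.10 and 0.08.

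Markers of other non-neuronal cells were higher in Positive nuclei too. For endothelium and pigment epithelium the median lay above the Müller median of 0.43, so the rise was not particular to Müller markers. Without Input 40 both medians lay below the Müller one (0.44 and 0.45 against 0.46), and without Positive 55 the endothelial one did (0.48 against 0.52). For astrocytes the median was 0.44, close to the Müller one. The astrocyte median was the lower of these without Positive 40, Positive 55 or Input 55 and after quantile normalization, and the higher in the other settings. Endothelial markers had a median log2 fold change of 0.55, with 13 of 14 higher. The tight-junction gene Cldn5 (Entrez gene 12741, chromosome 16, 18776847 to 18778262) had a mean log2 value of 0.62 ± 0.27 (SD, n = 3) in Positive and -0.14 ± 0.20 (SD, n = 2) in Input, a log2 fold change of 0.76 (SE 0.19). Adjusted over the list alone and over all genes, 0 endothelial markers were called, and the list's adjusted p in limma's camera was 3.06e-05 (adjusted p = 0.291 with an estimated correlation). Markers of the retinal pigment epithelium and choroid had a median of 0.51, with 9 of 11 higher. Tyrp1, a melanin synthesis gene (Entrez gene 22178, chromosome 4, 80834230 to 80851718), had a log2 fold change of 1.30 (SE 0.20), and Rpe65, the isomerase of the visual cycle in the pigment epithelium (Entrez gene 19892, chromosome 3, 159599181 to 159625307), had 1.29 (SE 0.25). Those 2, the melanin synthesis gene Dct (1.12) and the transporter gene Slc16a8 (0.51) were the 4 called when adjusted over the list alone, with 0 called over all genes. For this list the adjusted p in limma's camera was 1.03e-04 (adjusted p = 0.291 with an estimated correlation).

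Retinal astrocyte markers had a median log2 fold change of 0.44, with 9 of 10 higher, and 0 called over the list alone or over all genes. Gfap, the glial intermediate filament gene, had 0.73 (SE 0.26) and Slc1a2 had -0.05 (SE 0.07). The list's adjusted p in limma's camera was 0.00686 (adjusted p = 0.436 with an estimated correlation), and its median was 0.25 without Positive 40 and 0.27 after quantile normalization. Microglia and macrophage markers had a median of 0.28, with 13 of 17 higher and 0 called over the list alone or over all genes. The protease gene Ctss had 0.77 (SE 0.19), the complement gene C1qa 0.22 (SE 0.21) and Aif1 -0.46 (SE 0.30). The list's adjusted p in limma's camera was 0.0168 (adjusted p = 0.307 with an estimated correlation). It was 0.144 without Input 40, over a range of 0.00176 to 0.144 in 15 settings, and the median was 0.16 without Positive 40. Mural cell markers had a median of 0.23, with 9 of 10 higher and 0 called over the list alone or over all genes (adjusted p = 0.0168 in limma's camera, and adjusted p = 0.291 with an estimated correlation). Their adjusted p was 0.0765 without Positive 55 and 0.186 without Input 40, over a range of 0.00181 to 0.186 in 15 settings. Myelin genes had a median of 0.14 (adjusted p = 0.731 in limma's camera), which was 0.36 after quantile normalization, 0.24 without Positive 12, -0.01 without Positive 55, -0.02 without Input 40 and -0.01 without Input 55.

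Among signalling genes, members of the Wnt pathway had a median log2 fold change of 0.39, with 14 of 17 higher. The secreted antagonist gene Sfrp1 had 0.91 (SE 0.15), the transcription factor gene Lef1 0.78 (SE 0.23), and the feedback target Axin2 -0.05 (SE 0.09). Adjusted over the list alone, 4 were higher (Sfrp1, Tcf7l2, Dkk3 and Fzd7) and over all genes 0. Dkk3 is also among the Müller markers, and the median was 0.39 without it. The list's adjusted p in limma's camera was 3.06e-05 (adjusted p = 0.291 with an estimated correlation). TGF-beta and BMP pathway genes had a median of 0.21, with 15 of 18 higher, and 5 were called over the list alone (Bambi, Tgfbr2, Id3, Id2 and Tgfb1) and 0 over all genes. Bambi, a pseudoreceptor that dampens the pathway, had a log2 fold change of 0.67 (SE 0.09) and the ligand gene Tgfb1 had 0.73 (SE 0.18). In limma's camera the adjusted p was 1.03e-04 (adjusted p = 0.291 with an estimated correlation). Notch pathway genes had a median of 0.20, with 13 of 17 higher and 0 called over the list alone or over all genes (adjusted p = 0.00516 in limma's camera, and adjusted p = 0.291 with an estimated correlation). Without the 2 genes shared with the Müller list their adjusted p was 0.0210, with a median of 0.20. In the same libraries endothelial markers had a median of 0.55 and pigment epithelium markers a median of 0.51. The Notch list was the only list of the 32 past the threshold of fry, at an adjusted p of 0.0183, led by Hes1 while the ligand gene Jag2 had -0.36 (SE 0.15). Hippo and YAP pathway genes had a median of 0.14 (adjusted p = 0.0706 in limma's camera, and adjusted p = 0.444 with an estimated correlation), with the YAP target Ctgf at 0.87 (SE 0.20). The Hippo list passed without Positive 40 (adjusted p = 0.0438) and without Input 55 (0.0152), over a range of 0.0152 to 0.361 in 15 settings. Its median was 0.22 without Input 55 and 0.07 without Input 40 (adjusted p = 0.361), with 0 members called over the list alone or over all genes.

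Genes of Müller glial functions were mostly higher in Positive, and these lists share genes with the Müller list. Genes of the Müller visual cycle had a median log2 fold change of 0.26, with all 10 measured members higher and 0 called over the list alone or over all genes. The opsin gene Rgr had 0.80 (SE 0.20), and the list's adjusted p in limma's camera was 0.00160 (adjusted p = 0.291 with an estimated correlation). Without the 2 genes shared with the Müller list the adjusted p was 0.0140, with a median of 0.21. Rgr and Rlbp1 are also expressed in the retinal pigment epithelium, whose markers had a median of 0.51 in the same libraries. The median was 0.13 after quantile normalization. Ion and water homeostasis genes had a median of 0.25, with 13 of 16 higher and 0 called over the list alone or over all genes (adjusted p = 0.00668 in limma's camera, and adjusted p = 0.349 with an estimated correlation). Without the 4 genes shared with the Müller list their adjusted p was 0.105, with a median of 0.20. The gap-junction gene Gja1 had a log2 fold change of 1.74 with an SE of 0.76, and both libraries of animal 40 lay low. Within animals 40 and 55 its Positive value exceeded Input by 1.24 and 1.42.

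Glutamate and ammonia handling genes had a median log2 fold change of 0.17, with 8 of 12 higher and 0 called over the list alone or over all genes (adjusted p = 0.0450 in limma's camera, and adjusted p = 0.309 with an estimated correlation). The cystine transporter gene Slc7a11 had 0.56 (SE 0.12) and the transaminase gene Gpt2 had -0.24 (SE 0.10). The adjusted p was 0.0815 with the fixed replicate block, 0.0794 without Positive 12, 0.107 without Positive 55, 0.0536 without Input 40, 0.138 without Input 55, 0.0599 with a trend and robust prior and 0.275 after quantile normalization (median 0.05), over a range of 0.0268 to 0.275 in 15 settings. Without the 3 genes shared with the Müller list it was 0.0834, with a median of 0.15. Lipid genes had a median of 0.09, with 16 of 21 higher and 0 called over the list alone or over all genes (adjusted p = 0.0161 in limma's camera, and adjusted p = 0.444 with an estimated correlation). The apolipoprotein gene Apoe had 0.60 (SE 0.14). The adjusted p of the lipid list was 0.0555 without Positive 40, 0.0516 without Input 55 and 0.237 after quantile normalization, over a range of 0.00766 to 0.237 in 15 settings. Its median was 0.18 without Positive 55, 0.05 without Positive 40 and 0.04 after quantile normalization, and without the 3 Müller markers in it the median was 0.06 and the adjusted p 0.113.

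Reactive gliosis genes had a median log2 fold change of 0.31, with 18 of 24 higher and 0 called over the list alone or over all genes (adjusted p = 5.20e-04 in limma's camera, and adjusted p = 0.291 with an estimated correlation). Without the 2 genes shared with the Müller list the median was 0.21 and the adjusted p 0.00393. In the same libraries markers of retinal astrocytes, among them Gfap, had a median of 0.44, those of endothelium 0.55 and those of microglia 0.28. Ggta1 had 1.26 (SE 0.31), the protease inhibitor gene Serpina3n 0.82 (SE 0.24) and Timp1 -0.83 (SE 0.46). Transcription factors of retinal progenitors had a median of 0.17, with 12 of 19 higher and 0 called over the list alone or over all genes (adjusted p = 0.00820 in limma's camera, and adjusted p = 0.307 with an estimated correlation). The highest were Sox2 (0.48, SE 0.14) and Sox9, both also Müller markers, and Lin28b had -0.47 (SE 0.18). The adjusted p of the progenitor list was 0.0658 with the fixed replicate block and 0.0536 without Input 40, over a range of 0.00111 to 0.0658 in 15 settings. Its median was 0.08 without Positive 12, and without the 4 Müller markers the median was 0.03 and the adjusted p 0.113. Extracellular matrix genes went both ways, with a median of 0.08, or -0.02 without Positive 55 and 0.02 after quantile normalization (adjusted p = 0.179 in limma's camera), Sparc at 0.69 (SE 0.18) and the brevican gene Bcan at -0.83 (SE 0.26). Adjusted over the list alone 1 was higher, Timp3, and over all genes 0.

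Glycolysis genes had a median log2 fold change of 0.19, with 15 of 19 higher, led by the lactate dehydrogenase gene Ldhb at 0.36 (SE 0.15). Their adjusted p in limma's camera was 0.00133 (adjusted p = 0.444 with an estimated correlation), and it was 0.191 after quantile normalization (median 0.07), over a range of 4.00e-04 to 0.191 in 15 settings. Heat shock genes had a median of 0.23, with 11 of 13 higher (adjusted p = 0.00481 in limma's camera, and adjusted p = 0.359 with an estimated correlation), and their adjusted p was 0.117 after quantile normalization (median 0.12), over a range of 0.00221 to 0.117 in 15 settings. Immediate early genes had a median of 0.15, with 15 of 20 higher (adjusted p = 0.0203 in limma's camera, and adjusted p = 0.423 with an estimated correlation). Fosl2 had 0.49 (SE 0.16) and Egr3 -0.53 (SE 0.21). The adjusted p of the immediate early list was 0.0851 with the fixed replicate block, 0.0794 without Positive 12, 0.0749 without Positive 55, 0.254 without Input 40 and 0.0909 after quantile normalization (median 0.10), over a range of 0.00673 to 0.254 in 15 settings. Cell cycle genes had a median of 0.23, with 14 of 17 higher, the cyclin gene Ccnd2 at 1.26 (SE 0.33) and the kinase gene Cdk6 at -0.45 (SE 0.14). Their adjusted p in limma's camera was 0.0203 (adjusted p = 0.352 with an estimated correlation), and it was 0.125 with the fixed replicate block, 0.150 without Positive 12 and 0.0536 without Input 40, over a range of 0.0101 to 0.150 in 15 settings. In these 4 lists 0 members were called over the list alone or over all genes.

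Long noncoding RNAs retained in the nucleus had a median log2 fold change of -0.23, with 8 of 10 lower and 0 called over the list alone or over all genes. Miat had -0.61 (SE 0.23) and Snhg11 -0.51 (SE 0.16), while Neat1 had -0.07 and Malat1 had 0.27 (SE 0.12). The members Meg3, Mirg and Rian lie in 1 region of chromosome 12, described below, and are not independent. Limma's camera gave the list an adjusted p of 0.0450 (adjusted p = 0.523 with an estimated correlation). It was 0.0561 with the fixed replicate block, 0.0791 without Positive 12, 0.184 without Positive 40, 0.0601 without Input 40 and 0.105 without Input 55, over a range of 0.00458 to 0.184 in 15 settings. The 77 ribosomal protein genes had a median of 0.03 (adjusted p = 0.271 in limma's camera). With an estimated correlation, which was 0.845 on all 5 libraries, the adjusted p of their list was 0.8895. Without Positive 55 their median was 0.13 (adjusted p = 5.04e-07, over a range of 5.04e-07 to 1.00 in 15 settings), and it was -0.06 after quantile normalization, -0.05 without Positive 12, -0.02 without Positive 40, 0.06 without Input 40 and 0.01 without Input 55. None of the genes in the file was mitochondrially encoded, so that list was not tested.

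The library Positive 12 stood apart from the other 4 at sex-linked genes, which were chosen after their values were seen. Its log2 value of Xist, the noncoding RNA of the inactive X chromosome, was -10.46, with a gap of -10.32 to the lowest of the others, and those of the Y-linked genes Ddx3y and Uty lay 8.38 and 6.71 above the highest. Its value of the Y-linked gene Usp9y was -0.09, within the range of the others. Xist, Ddx3y and Uty thus point to a difference in sex between animal 12 and the other animals, and Usp9y does not. Positive 12 has no Input partner here, so such a difference lies on the Positive side alone. With X- and Y-linked genes left out, limma called 0 genes, and 20 lists were higher and 2 lower in camera with the preset correlation. Without Positive 12, limma called 0 genes with 1678 at an unadjusted p under 0.05, and 17 lists were higher and 0 lower.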

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

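The settings without X- and Y-linked genes, without genes at a shared floor, with only genes passed in both conditions, with the trend alone and with the robust prior alone were chosen after the data were seen. The count of called genes was 0 higher and 0 lower in every setting run but 2, the random replicate block (4 higher, 7 lower) and a threshold of adjusted p under 0.1 (2 higher, 3 lower), which admits more genes by construction. In the first case the cause was not tested. Of the 159 named genes under 15 settings of limma's gene test, 2362 values stayed on the same side of the threshold, 5 became called (Oca2, Slc25a21, AF357355, 1700109G14Rik and Ssxb2, with the random block) and 0 reversed. A change of sign counted as reversed only where the gene was called in either fit. The main fit called 0 genes, so changes of sign in uncalled genes were not counted, and the 0 does not show that directions were stable. The count at an unadjusted p under 0.05 was 2334, 4305 with the random block and 1264 after quantile normalization, and 930 to 3188 leaving out 1 library at a time. The Müller list was higher in all 15 settings of camera with the preset correlation, with medians of 0.30 to 0.52 and an adjusted p of at most 1.14e-09, but its median of 0.43 did not pass with an estimated correlation (adjusted p = 0.311) or with fry, which sets it against no other genes (adjusted p = 0.103); an estimated correlation of 0.449 between its genes widens the error by construction. The astrocyte, endothelial, pigment epithelium, ion and water, Notch, Wnt, TGF-beta, gliosis and Müller visual cycle lists also passed in all 15. Of lists, 20 were higher and 3 lower. These counts were 16 and 0 with the fixed replicate block, where the calls of the cone, bipolar, long noncoding RNA, glutamate, immediate early, cell cycle and progenitor lists were lost. That block also takes Positive 12 out of the contrast, and of these calls all but the progenitor one were lost without Positive 12 alone, so the losses cannot be put down to the block alone. The counts were 20 and 2 with the random replicate block, which ended that of the cone list; the paired fits changed no other call of a list. They were 14 and 1 after quantile normalization, 0 and 0 with an estimated correlation, and 1 and 0 with fry, and the cause was not tested. Calls were also lost for lists whose estimated correlation lay below the preset 0.01. Among these were the pigment epithelium (-0.02), Notch (-0.05), mural (-0.04) and Müller visual cycle (-0.02) lists. A higher correlation between genes therefore cannot account for every loss with an estimated correlation. Leaving out 1 library at a time gave 14 to 19 lists higher and 0 to 3 lower (0 without Positive 12 or Input 40, 1 without Positive 55), with a Müller median of 0.35 to 0.52. Where 1 Input library remained, it was assumed to vary like the Positive ones. Not run were scaling by trimmed means, 2 pseudocounts and 2 filters on low values, since the values hold no level or linear scale. The depth is unknown, so what it limits cannot be stated.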

Other observations

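The gene groups and the region in the next 2 paragraphs, the tests of the rod share, of gene length and of the mural markers, and the sex-linked and animal 40 values were chosen after the data were seen. Among Gene Ontology terms, genes of the proteasome core complex, the barrel that degrades tagged proteins, were higher in Positive nuclei: 16 of 17 had a positive log2 fold change, with a median of 0.25, and Psmb7 had 0.44. Genes with histone-lysine methyltransferase activity were lower in 22 of 26, with a median of -0.16, and in 18 of them all 3 Positive libraries lay below both Input libraries. Dot1l, the H3K79 methyltransferase, had -0.56 and Mll2 -0.46. Genes of voltage-gated calcium channels were lower in 20 of 24, with a median of -0.25, among them Cacna1h (-0.56), Cacna2d2 (-0.49) and Cacna1e (-0.45), and genes of cilium assembly were lower in 44 of 62, with a median of -0.11. In limma's camera with the preset correlation the adjusted p was 0.00386 for the proteasome core, 0.00514 for the methyltransferases, 0.0131 for the calcium channels and 0.0256 for cilium assembly. With an estimated correlation the adjusted p was 0.786, 0.786, 0.798 and 0.786, and 0 of the 1419 terms passed, against 69 higher and 17 lower with the preset one. Gonad development, Wnt-protein binding and Wnt-activated receptor activity, all higher in Positive, ranked above the terms named here. Random lists matched on gene length were not drawn for any term.

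Genes of the imprinted region from Meg3 to Mirg (mm10 chromosome 12, 109540996 to 109749457) were lower in Positive in 13 of 13 cases, with a median log2 fold change of -0.51. In 6 of the 13 all 3 Positive libraries lay below both Input libraries. The count of 13 is of group means, and 6430411K18Rik had only -0.03 (SE 0.32). Within animal 40 every gene was lower in Positive, while within animal 55 6430411K18Rik and Mir409 were higher, by 0.21 and 0.12. Meg3, a maternally expressed noncoding RNA, had -0.51 (SE 0.16), Mirg -0.47 (SE 0.19) and Rian -0.23 (SE 0.17), and the snoRNA gene AF357355, inside Rian, had -1.80 with 2 libraries at a shared floor. These genes overlap and can share reads, so the 13 are not independent, and 3 of them had an unadjusted p under 0.05 in limma.

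Müller markers were higher in Positive than in Input, where a smaller share of rod nuclei would raise the markers of all other retinal cells alike, but the Müller median exceeded that of 73 cone, bipolar, amacrine, horizontal and ganglion cell markers by at least 0.391 in each of the 3 Positive libraries, which argues against it as the whole cause. Gene length is argued against as well, since the list's median lay above all random lists matched on it (percentile 100). The median also lay above all random lists matched on residual spread (percentile 100), but genes of such lists need not move together. The Müller markers had an estimated correlation of 0.449, so that comparison cannot decide whether they drifted together. The 10 splits of the libraries into 3 and 2 are too few for a share under 0.05; the real split gave 23 lists with the preset correlation (1 of 10 splits gave as many), the highest other 17, and the other 3 that part both animal pairs 0 to 13, although splits that keep the Input libraries together, such as those with 17 and 13, keep part of the real contrast. The Müller list itself passed limma's camera with the preset correlation in 6 of the 9 other splits, 3 of which keep the Input libraries together (adjusted p of 1.31e-10, 2.62e-07 and 0.0106) and 3 of which part them (0.0166, 0.0249 and 0.0369), against 3.00e-12 in the real split. A larger share of Müller nuclei in the captured fraction, the difference the design names, stays open as a candidate explanation, and its size was not estimated.

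Endothelial and pigment epithelium markers were higher in Positive as well. The medians of both lists lay above at least 99.97% of random lists matched on residual spread. For the pigment epithelium list, whose estimated correlation was -0.02, this argues against drift of genes with a large spread as the whole cause. The list's median was 0.80 within animal 40 and 0.31 within animal 55. Its median difference between the Input libraries was -0.05 (Input 40 minus Input 55). Its members Tyrp1 and Rpe65, however, lay at -0.39 and -0.34 in Input 40 and at 0 in Input 55. The endothelial list had a median difference of -0.25 between the same Input libraries, so drift stays open for it. Nuclei of other non-neuronal cells that came with the beads may contribute, although the protocol, whose text also names brain tissue, spun out undissociated tissue, mostly vessels, beforehand, and the markers of mural cells, which neighbour the endothelium and share Notch3 with the Notch list, were higher by at least 0.200 in each Positive library. Since that bound was set after the values were seen, it does not decide the matter, and such carry-over cannot be told apart from a gain of these transcripts in tagged nuclei.

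Many genes had an unadjusted p under 0.05 and 0 passed the adjusted threshold. The real split gave 2334 such genes and 2 of the 10 splits gave as many, the other being Positive 12 and Positive 40 against the remaining 3 libraries with 3042, and 10 splits are too few for a share under 0.05. Among the 4 splits that part both animal pairs, the other 3 gave 327 to 728, and the splits with 3042 and 728 keep the Input libraries together. In the split of 3042 Positive 55 stands with the Input libraries, and its SD over all genes was 0.37, against 0.49 in Positive 12 and 0.47 in Positive 40.

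At Fbln1, a matrix gene, each library of animal 40 lay below its counterpart of animal 55. It had log2 values of -2.21 in Input 40 and -0.80 in Positive 40, against 0.00 in Input 55 and 1.17 in Positive 55, and within the animals Positive exceeded Input by 1.41 and 1.17. The Positive 12 values of Xist (-10.46) and Ddx3y (8.40) have no Input library of animal 12 beside them here.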
